A study of Mus musculus with 4 samples.

How the data were processed

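Total RNA of mouse embryonic stem cells was measured on 4 GeneAtlas arrays of 1 strip, strip 2, with 1 array for each of 4 groups. All cells lacked Prdm14 and were grown with 2 inhibitors and leukemia inhibitory factor on STO fibroblast feeder cells, per the labels' protocols. They carried an empty vector, mouse PRDM14, sea urchin PRDM14, or sea urchin PRDM14 together with sea urchin CBFA2T. A different strip that the series' design text mentions was not used here.

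The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes of each probe set. The RMA version, the arrays normalized together and the genome build are not given in the sources used here. The medians of the 4 arrays lay between 4.54 and 4.55, so a shift shared by most genes on 1 array would not show in these values. RMA values carry no detection call, and a dim gene's fold is pulled toward 1 by background.

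The table held 41345 probe sets. Of these, 23521 were paired with 1 gene, 1814 with several genes and 16010 with none in the platform annotation. Entrez identifiers of 23328 of the 23521 were found in the RefSeq table of GRCm38.p6, and 0 symbols needed an update. That table was used for names, for chromosome membership and for the order of neighbouring genes, and no coordinates are printed. Gene values came from the probe set with the highest mean over the 4 arrays, which gave 22180 genes, 1082 of them with several probe sets. A gene was kept when its highest value over the 4 arrays reached 4.84, the median of all named probe-set values, and 12042 genes passed. A gene that is bright on 1 array only thus passes through that array, which favours large differences.

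With 1 array per group there is no replicate error, so no test was made and no p-value is given. Differences between arrays were called by size, at 2-fold, which is 1 on the log2 scale. The 4 main comparisons set each PRDM14 array against the empty vector array, and the array with CBFA2T against the array with sea urchin PRDM14 alone. Both sea urchin arrays were also set against the mouse PRDM14 array. The thresholds, the comparisons, 25 gene lists, all alternatives but the last below, and the rule for named genes were fixed before the data were examined.

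The named genes were Prdm14, Cbfa2t2, Cbfa2t3 and Runx1t1, then up to 10 genes with the largest positive and up to 10 with the largest negative difference past 2-fold in each main comparison. From that naming, not from the counts, symbols of predicted genes, small RNAs and receptor families were left out by their prefix or by containing Rik. Small RNAs with other symbols, such as Rny1 and AF357355, stayed in. For each list, members past 2-fold were named, or the member with the largest absolute difference where none passed, with at most 4 per list. Genes past 2-fold in both of the main differences that share no array were named as well. Genes named outside this rule are described as chosen after their values were seen.

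For each gene list the median log2 difference was set among 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1). A list counted as outside when its percentile was below 2.5 or above 97.5. The percentile describes these arrays and is not a test of the conditions. A gene could belong to several lists. An older symbol in a list was replaced only where it was no gene's current symbol and pointed to 1 gene.

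Differences against the same empty vector array share its chance values. Correlations across genes were therefore computed for pairs of differences without a shared array, and those with a shared array were set beside 100 simulations of unchanged groups. On simulated data for the mouse PRDM14 against empty vector comparison over 12042 genes, 44% of genes with a true 2-fold change were called, and 100% of those with a 3-fold change. None of the unchanged genes was called there. The simulated noise was Gaussian, with a spread taken from the middle of the real differences, which made a 2-fold difference by chance very unlikely. The simulation therefore gives no rate of false calls for the real arrays. A true 2-fold change lies at the threshold itself, where the direction of the noise decides the call. The 44% is thus no measure of the sensitivity of these arrays.

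The alternatives were a 1.5-fold threshold, no filter, a stricter filter at 5.65 (the 75th percentile, 6377 genes), cyclic loess between the arrays, the mean of all probe sets of a gene, and leaving out the symbols that the naming rule leaves out. Leaving out chromosomes 11 and 16 was added after the chromosome medians had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.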

Results

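Gene expression was measured in mouse embryonic stem cells without Prdm14, a PR domain zinc finger protein of naive pluripotent and germ cells. The cells carried an empty vector, mouse PRDM14, sea urchin PRDM14, or sea urchin PRDM14 with sea urchin CBFA2T, a co-repressor family whose mouse member Cbfa2t2 binds PRDM14. Each group had 1 array, so no value below has a replicate error, and the number of arrays limits the precision. The arrays were close to one another, with Pearson's r across all probe sets between 0.986 and 0.989. The SD of the log2 differences across genes was 0.16 for mouse PRDM14 and for sea urchin PRDM14 against the empty vector, and 0.20 for sea urchin PRDM14 and CBFA2T.

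The Prdm14 probe set did not separate the groups. Its log2 value was 5.71 with the empty vector, 5.57 on the array labelled mouse PRDM14, 5.77 on the array labelled sea urchin PRDM14 and 5.53 on the array labelled sea urchin PRDM14 and CBFA2T. The array labelled mouse PRDM14 thus showed no higher Prdm14 signal than the empty vector array. Where the probes lie relative to the deleted part and to the introduced sequence is not given in the sources used here, so the labels could not be checked from this gene. Each group name below therefore means the array labelled with it. Mouse Cbfa2t2 lay between 5.10 and 5.62, Cbfa2t3 between 5.81 and 5.88, and Runx1t1 between 5.53 and 5.67, none of them 2-fold apart between any of the arrays.

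The first comparison asks what mouse PRDM14 does in cells that lack it. On the array labelled mouse PRDM14, 7 genes were at least 2-fold higher and 3 at least 2-fold lower than on the empty vector array. The higher genes included Rex2 (log2 difference 1.26) and Zfp992 (1.09), zinc finger genes of chromosome 4, and Rny1 (1.04), a small cytoplasmic RNA. The other 4 were small RNAs that the naming rule leaves out by symbol. The lower genes were AF357355 (-1.96), a small nucleolar RNA, and Rian (-1.01), an imprinted long noncoding RNA gene, both of chromosome 12, and Gja1 (-1.003), which encodes the gap junction protein connexin 43. Rian is dim with mouse PRDM14 (4.56), below the filter value of 4.84. Gja1 slipped under 2-fold after cyclic loess (-0.997).

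Naive pluripotency genes were slightly higher with mouse PRDM14. None of the 25 list members past the filter was 2-fold apart, but 16 of 25 differences were above 0, and their median of 0.12 lay above 9996 of the 10000 random lists. Klf4 differed by 0.28, Jam2 by 0.28, Tfcp2l1 by 0.25 and Klf5 by 0.21, while Nanog differed by -0.08 and Laptm5, the member with the largest absolute difference, by -0.39. Klf4, Jam2, Tfcp2l1, Klf5 and Nanog were chosen after their values were seen.

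Of the lists of other developmental states, 2 lay below the random lists with mouse PRDM14. The formative and primed epiblast list had a median of -0.09 (percentile 2.13, 12 of 19 members below 0), or -0.24 with the stricter filter, with its largest difference in the DNA methyltransferase gene Dnmt3b (-0.46). The primitive endoderm list had a median of -0.11 (percentile 0.26, 15 of 18 members below 0). Its largest difference, in Sparc, was 0.37, opposite to the list. The interferon response list had a median of -0.15 over 9 members (percentile 0.87), which became -0.01 with no filter on dim genes and -0.06 (percentile 16.1) without chromosomes 11 and 16, inside the random lists both times. The other 20 lists with values lay inside the central 95% of random lists, with medians between -0.10 and 0.09. Among single genes, Bmp4 had a difference of 0.79 and Phgdh one of -0.58.

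Sea urchin PRDM14 alone gave 4 genes at least 2-fold higher and 0 lower than the empty vector. This comparison asks whether the sea urchin protein acts in mouse cells. Rex2 (1.63) and Zfp981 (1.38), again zinc finger genes of chromosome 4, were the 2 that are not small RNAs. Zfp981 is dim on the empty vector array (4.62). The naive pluripotency list lay lower, not higher, with a median of -0.10 (percentile 0.01, 16 of 25 members below 0), and Laptm5 differed by -0.47. With the mean of all probe sets of a gene this median was -0.02 (percentile 13.3), so its place outside the random lists depends on the probe set used. It was -0.06 with no filter and with the stricter filter, still outside.

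The unfolded protein and amino acid stress list also lay lower with sea urchin PRDM14, with a median of -0.13 (percentile 0.02, 10 of 15 members below 0). Its largest difference was in Cth, an enzyme of cysteine synthesis (-0.62). Trib3 (-0.382) and Asns (-0.365) were lower too. The unfolded protein genes Hspa5 (0.337) and Xbp1 (0.332) were higher and Herpud1 (0.003) hardly differed, so the list did not move as a whole. All of these but Cth were chosen after their values were seen. The trophoblast list had a median of -0.10 (percentile 0.52), led by Ets2 (-0.51), and lay inside the random lists with no filter (-0.06) and with the stricter filter (-0.06). The other 21 lists lay inside, with medians between -0.06 and 0.07. Suz12, a Polycomb repressive complex 2 subunit gene of chromosome 11, had a difference of 0.77 and the imprinted gene Plagl1 one of -0.86.

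Against mouse PRDM14 directly, the array labelled sea urchin PRDM14 had 6 genes higher and 1 lower. The naive pluripotency list had a median of -0.12, below all 10000 random lists, and 18 of its 25 members were below 0.

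**Figure D1:**
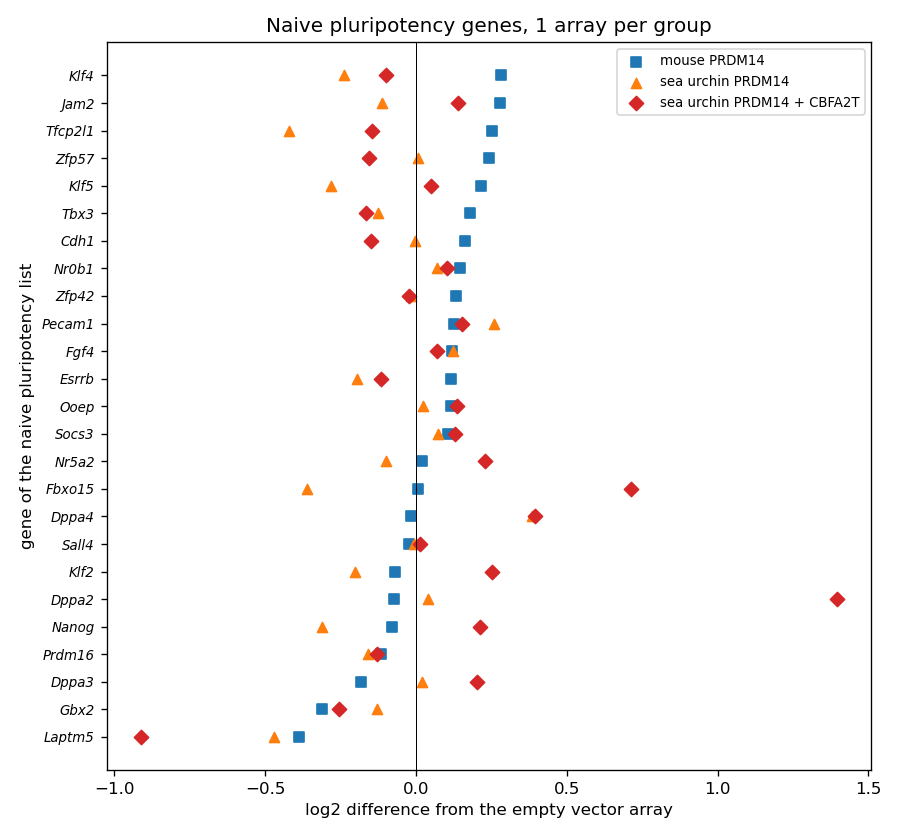
Log2 difference of each of the 25 naive pluripotency genes from the empty vector array, for the mouse PRDM14 array (squares), the sea urchin PRDM14 array (triangles) and the sea urchin PRDM14 and CBFA2T array (diamonds), 1 array per group. Most genes lie within 0.5 of 0, the mouse PRDM14 median is 0.12 and the sea urchin PRDM14 median is -0.10, and Dppa2 stands apart at 1.39 on the array with CBFA2T.

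The array labelled sea urchin PRDM14 and CBFA2T differed most from the empty vector by count, with 19 genes at least 2-fold higher and 6 lower. The highest with established names belonged to Zscan4, a zinc finger family of the 2-cell embryo and of rare cells in stem cell cultures. Zscan4e was higher by 4.25 on the log2 scale, Zscan4b by 3.93, Zscan4d by 2.25 and Zscan4c by 2.16. The other 3 of the 7 genes at least 4-fold higher were the predicted genes Gm5662 (3.87), Gm11543 (3.69) and Gm2046 (3.38), named after their values were seen. Usp17le (1.75), Pramel19 (1.63) and Dppa2 (1.39) were higher too. Gm5662 and Gm11543 were at 2.47 and 2.87 on the empty vector array, and Gm2046, Zscan4e, Zscan4b, Zscan4d, Usp17le and Pramel19 between 3.81 and 4.47, below the filter value, so their folds rest on values near background. Also higher were the zinc finger genes Rex2 (1.93), Zfp981 (1.46) and Zfp992 (1.18). Suz12 was higher by 1.01, just past the threshold.

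The 6 lower genes were Apela (-1.82), a peptide ligand gene, Sfrp1 (-1.61), a secreted Wnt antagonist gene, Trh (-1.53), the gene of thyrotropin-releasing hormone, AF357355 (-1.23), Rian (-1.06) and Cth (-1.02). Apela (3.32) and Rian (4.51) are below the filter value on the CBFA2T array. Most cholesterol synthesis genes lay lower. The list median was -0.26, below all 10000 random lists, with 13 of 15 members below 0, although none was 2-fold apart. Nsdhl differed by -0.65. Fdft1 went the other way (0.46), and was also higher with mouse PRDM14 (0.47) and sea urchin PRDM14 alone (0.36). The glycolysis and hypoxia list had a median of -0.13 (percentile 0.02, 16 of 22 members below 0), with the largest difference in Ddit4 (-0.41). The unfolded protein and amino acid stress list had a median of -0.15 (percentile 0.03, 12 of 15 members below 0). Its members Xbp1 (0.30) and Hspa5 (0.047), picked after their values were seen, were above 0. The imprinted genes had a median of -0.12 (percentile 0.22) and the primitive endoderm list one of -0.09 (percentile 1.01). The last of these lay inside the random lists with the stricter filter (percentile 3.60) and without chromosomes 11 and 16 (percentile 2.89).

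Housekeeping genes moved with these lists: their median was -0.09 (percentile 0.46, 15 of 22 members below 0), led by Pgk1 (-0.40), which is also on the glycolysis list. The fibroblast list, which holds feeder cell markers, had a median of -0.00 (percentile 36.3, 15 of 30 members above 0).

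The comparison of the 2 sea urchin arrays asks what CBFA2T adds to sea urchin PRDM14. With CBFA2T, 16 genes were at least 2-fold higher and 6 lower, and 5 of the 16 were predicted genes without an established name. The totipotent-like 2-cell stage list had a median of 0.59 over 9 members, above all 10000 random lists, and 3 of the 9 were past 2-fold. The size of this median depends on the members kept: it was 0.20 with no filter, 1.57 with the stricter filter and 0.35 without chromosomes 11 and 16, each above all random lists. Against the empty vector the median was 0.46, and 0.24, 1.75 and 0.34 in the same alternatives. The filter takes the highest array, and Zscan4d, Usp17le and Tmem92 pass it only through the CBFA2T array. Zscan4e differed by 4.58 (23.8-fold), Zscan4b by 4.15 (17.7-fold), Zscan4d by 2.33, Zscan4c by 1.91 and Usp17le by 1.57. Of the 7 genes at least 4-fold higher, 4 were predicted genes: Gm5662 (3.91), Gm11543 (3.59), Gm2046 (2.60) and Gm2022 (2.13), again named after their values were seen. On the other 3 arrays Zscan4e, Zscan4b, Zscan4d and Usp17le were at 3.49 to 4.62 and Gm5662 and Gm11543 at 2.42 to 3.09, again near background.

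Other genes higher with CBFA2T were Pramel19 (1.60, from a dim 3.84), Elobl (1.43, from 4.60), Calcoco2 (1.37), Dppa2 (1.35) and Fbxo15 (1.07). Dppa2 is bright, at 9.02 with CBFA2T and 7.66 without. The lower genes were AF357355 (-1.83), Trh (-1.37), the Nodal co-receptor gene Tdgf1 (-1.16), Sfrp1 (-1.08), Apela (-1.03) and the ephrin receptor gene Epha2 (-1.003). After cyclic loess Epha2 slipped under 2-fold (-0.997). Against the empty vector, Fbxo15 (0.71), Tdgf1 (-0.67) and Epha2 (-0.81) were not past 2-fold. Elobl was at 5.29 with the empty vector and 6.02 with CBFA2T. For these genes the empty vector value lay between those of the 2 sea urchin arrays. Between the 2 sea urchin arrays, cholesterol synthesis (-0.18, percentile 0.01), glycolysis and hypoxia (-0.11, percentile 0.10) and primitive endoderm (-0.08, percentile 1.76) lay lower. Cyp51, an enzyme of cholesterol synthesis, differed by -0.67. The DNA methylation and demethylation list had a median of 0.10 (percentile 98.9), with 7 of 12 members above 0 and the largest difference in Uhrf1 (0.22); against the empty vector its median was -0.01 (percentile 32.5). The naive pluripotency list had a median of 0.05 (percentile 95.7), inside the random lists, but 0.07 and outside with the stricter filter (percentile 98.2). Against the empty vector it was 0.07 (percentile 94.3), and -0.005 without chromosomes 11 and 16. The primitive endoderm list was also inside with no filter (-0.05) and with the stricter filter (-0.08, percentile 3.99).

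**Figure D2:**
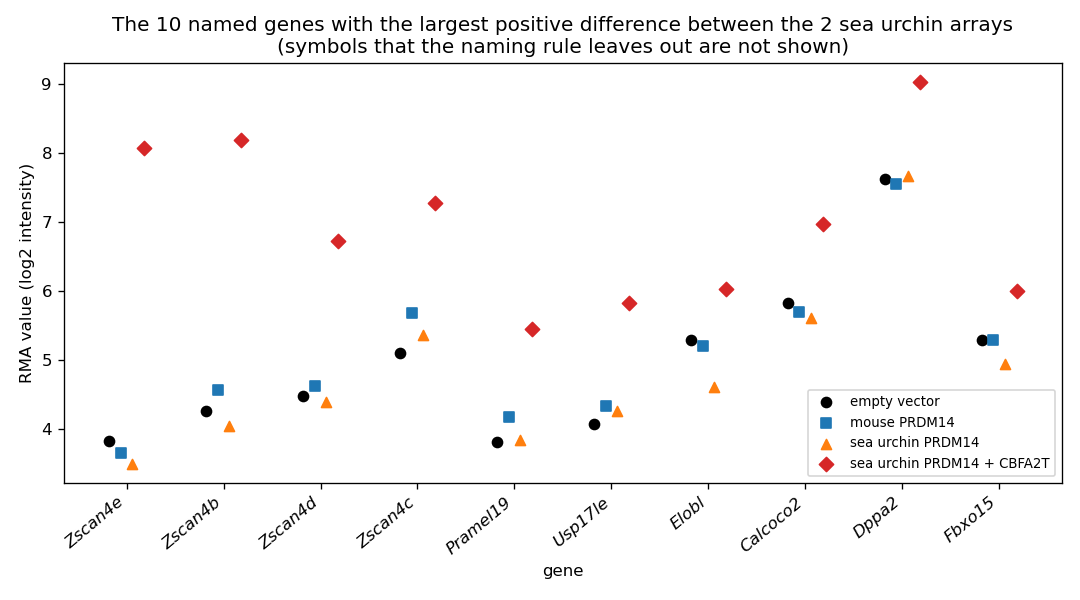
RMA value (log2 intensity) on each of the 4 arrays for the 10 named genes with the largest positive difference between the 2 sea urchin arrays, symbols that the naming rule leaves out not shown. In all 10 genes the sea urchin PRDM14 and CBFA2T array (diamonds) lies above the other 3 arrays, with Zscan4e at 8.07 against 3.49 to 3.82.

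Over the 4 main comparisons, 19 of 96 list medians lay outside the central 95% of random lists, where 4.8 would for independent lists of unrelated genes. These lists hold related genes and share some of them, and the comparisons share arrays. The excess over 4.8 therefore does not show that the conditions differ. Lists of neural and mesodermal genes, proliferation, p53 targets and core pluripotency lay inside in all 4. The PRDM14 partner list and the lists of FGF and ERK genes, Polycomb repressive complex 2, germ cell genes and silenced germline genes lay inside as well. The germ cell list came close with CBFA2T added (percentile 97.45), as did the motor neuron and early neuron list with mouse PRDM14 (97.43). The primitive streak and mesoderm list came close with sea urchin PRDM14 (97.17). Against mouse PRDM14 the germ cell list lay outside on the sea urchin PRDM14 array (98.05) and with CBFA2T added (99.22). Against the empty vector, however, its median was -0.09 with mouse PRDM14 (percentile 4.14) and -0.04 with sea urchin PRDM14 alone (percentile 13.7). Some other lists lay outside against mouse PRDM14 too, among them p53 targets with CBFA2T added (98.84). The sex-linked list had 0 genes past the filter.

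**Figure D3:**
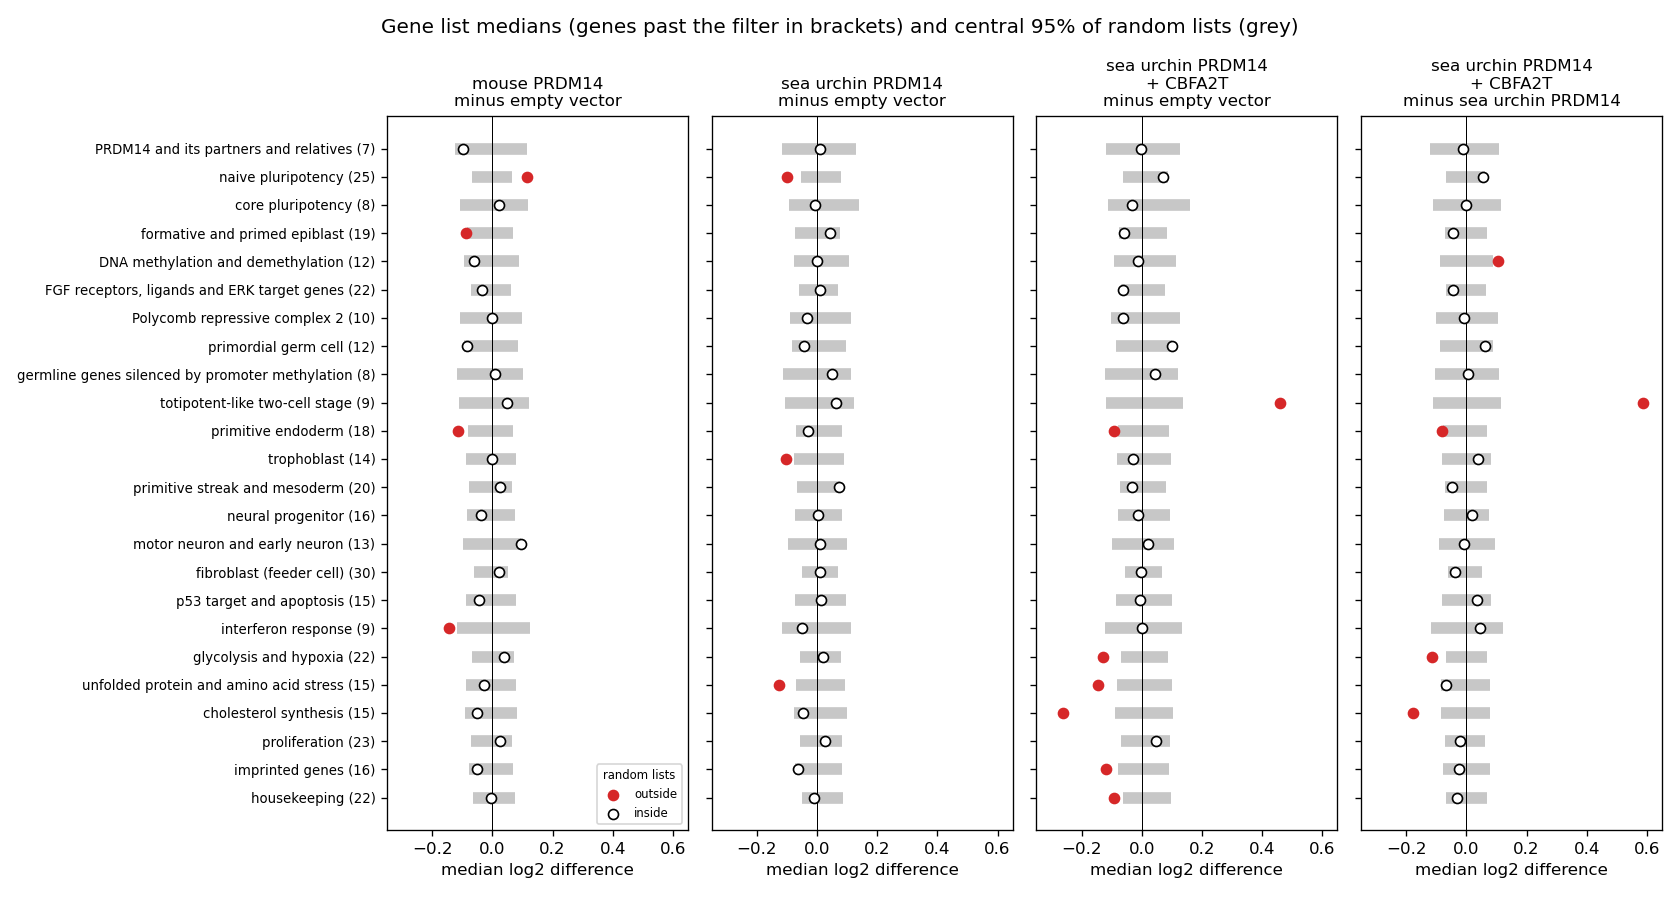
Median log2 difference of each gene list (points) in the 4 main comparisons, with the central 95% of random lists of the same size and expression as grey bars and the number of genes past the filter in brackets. Filled points lie outside the bars. The 2-cell stage list lies at 0.46 and 0.59 (0.24 and 0.20 with no filter) and cholesterol synthesis at -0.26 and -0.18.

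Genes of chromosome 11 lay slightly higher on both sea urchin arrays than on the empty vector array. Over 1069 genes past the filter, assigned by the GRCm38.p6 annotation, the median difference was 0.057 with sea urchin PRDM14 and 0.065 with CBFA2T added, against -0.004 with mouse PRDM14. Chromosome 16 genes (361) had medians of 0.072 with CBFA2T added and -0.005 with sea urchin PRDM14 alone. These chromosomes were singled out after the values were seen. Of the 25 genes called for the CBFA2T array against the empty vector, 5 lie on chromosome 11 and 1 on chromosome 16.

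**Figure D4:**
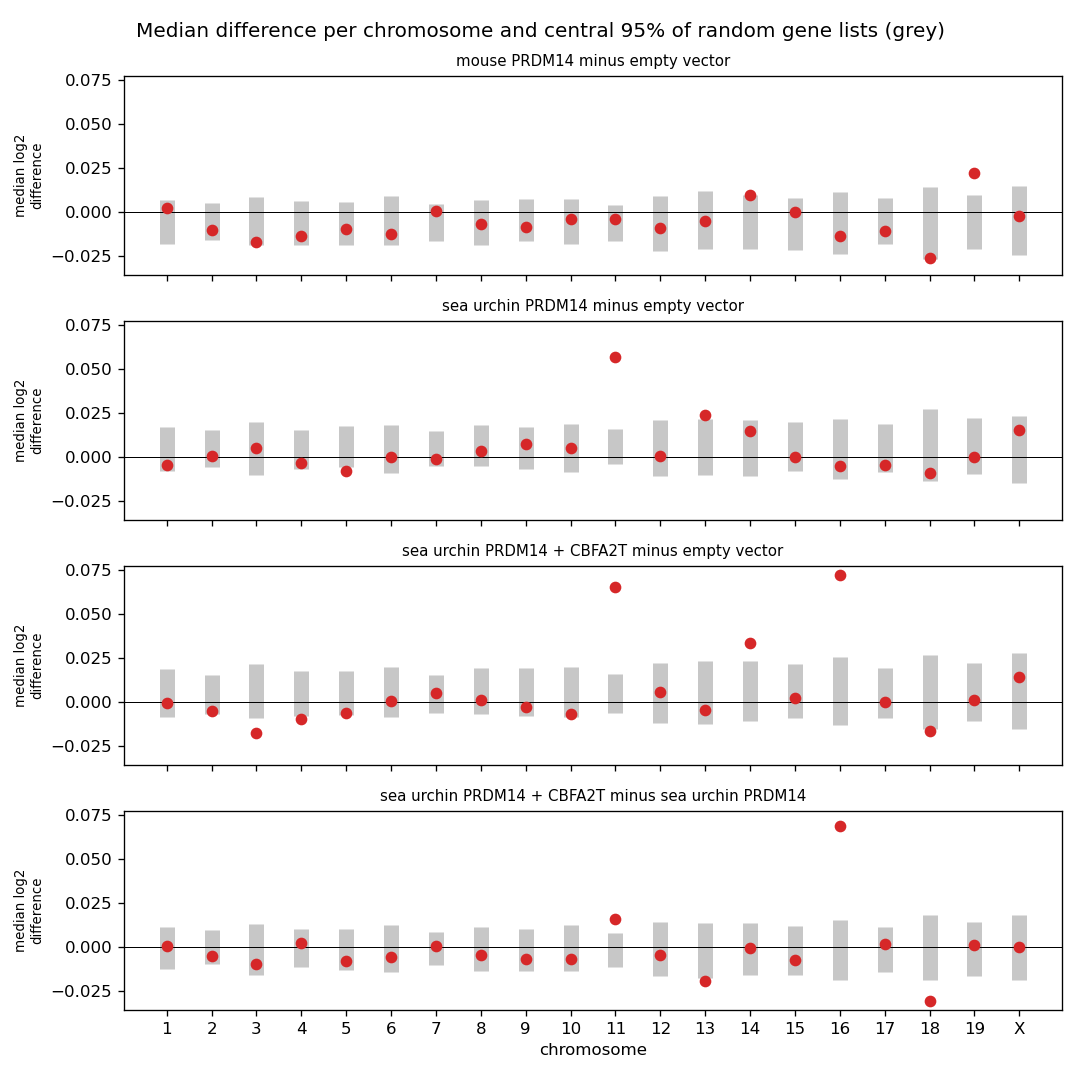
Median log2 difference of the genes of each chromosome (points) in the 4 main comparisons, with the central 95% of 1000 random gene lists as grey bars. Chromosome 11 stands above the bars with sea urchin PRDM14 (0.057) and with CBFA2T added (0.065), and chromosome 16 with CBFA2T added (0.072). By less, so do chromosome 14 with CBFA2T added (0.034), chromosome 13 with sea urchin PRDM14 (0.024) and chromosome 19 with mouse PRDM14 (0.022). Chromosomes 16 (0.069) and 11 (0.016) also stand above them between the 2 sea urchin arrays, and some others lie below the bars.

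The study's groups also allow the question whether adding CBFA2T to sea urchin PRDM14 moved genes in the way mouse PRDM14 did. Across 12042 genes, the mouse PRDM14 minus empty vector difference and the CBFA2T minus sea urchin PRDM14 alone difference, which share no array, had Pearson's r of 0.09 and Spearman's rho of 0.07. The other 2 pairings without a shared array gave r of 0.15 and 0.06. Genes are not independent replicates. AF357355 was past 2-fold in both, lower each time. Of the 7 genes higher with mouse PRDM14, 3 were higher with CBFA2T than without. The median of the 7 was -0.18, which turned to 0.033 with the stricter filter and at 1.5-fold and to 0.30 without the symbols that the naming rule leaves out (Rex2, Zfp992 and Rny1 remained). Of the 3 lower genes, 0 were higher with CBFA2T than without, and their median was -0.94. AF357355 and Rian among them lie close together on chromosome 12, AF357355 within 5 genes past the filter of Rian. At 1.5-fold the median was -0.14, and 5 of 20 genes were higher. The response of the higher genes has no settled direction. That of the lower genes was negative in every alternative. The alternatives reused the same few genes, however, and only the 1.5-fold threshold added others. The size of this response is thus not settled, and it rests on few genes.

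Differences that share the empty vector array correlated at 0.45 for mouse and sea urchin PRDM14, 0.44 for mouse PRDM14 and the CBFA2T array, and 0.51 for the 2 sea urchin arrays. Unchanged groups against 1 shared control gave 0.50 in simulations, a value that follows from sharing a control when all groups have equal spread. The covariances were 0.0111, 0.0137 and 0.0155 beside a simulated 0.0151. Without replicates, the simulated spread came from the real arrays, so it already holds any difference between the groups. The simulated values therefore cannot show whether the PRDM14 arrays share an effect. Rex2 was past 2-fold in all 3 comparisons with the empty vector. Zfp992, AF357355 and Rian were called for mouse PRDM14 and for the CBFA2T array, and Zfp981 and Snord1b for both sea urchin arrays. As the empty vector array is shared, part of this overlap can come from its own values.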

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

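The tests of all 3 patterns below were chosen after the results were seen, and the chromosome pattern was found by looking over at least 240 medians (20 chromosomes, 6 comparisons, 2 gene sets).

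Zscan4 genes were higher on the array labelled sea urchin PRDM14 and CBFA2T in probe sets outside the main measurement too: both probe sets that stand for 6 Zscan4 genes at once differed from the empty vector, by 3.50 and 4.47, from values near background (3.18 and 3.36). The 2-cell stage list had a median between the 2 sea urchin arrays of 0.60 after cyclic loess, above all random lists. Cyclic loess removes only smooth trends with intensity, and the random lists were already matched on mean expression. This result could thus hardly have come out otherwise and says little about intensity-dependent normalization. Sharing of probe sets between paralogs stays open, since the 3 list members past the filter outside the Zscan4 and Usp17l families had a median of 0.11 (percentile 86.9); without the filter, 9 such members had the same median at percentile 98.2, but most are dim. Single-locus names such as Dppa2 (1.39) were also higher, though these were picked for being so. Co-expression of CBFA2T and chance differences between cultures cannot be told apart with 1 array per group, and Zscan4 cells may differ in number between cultures.

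The naive pluripotency list lay in opposite directions for the mouse (0.12) and sea urchin (-0.10) proteins against the empty vector. The choice of 1 probe set per gene does not account for the mouse part, as the mean of all probe sets gave 0.093 (percentile 99.7), but it may account for the sea urchin part, where the mean gave -0.023 (percentile 13.3). The gap between the 2 proteins is not explained by it, as their direct median of -0.12 was -0.107 (percentile 0.04) with the mean. A different share of feeder cells stays open: the fibroblast list had a median of 0.003 between the 2 arrays, with 16 of 30 members above 0, which decides nothing. Chance differences between single cultures stay open with 1 array per group.

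Chromosome 11 genes were higher on both sea urchin arrays, with medians of 0.057 and 0.065 against the empty vector over 1069 genes, and -0.004 with mouse PRDM14. After cyclic loess the sea urchin PRDM14 median was 0.052, above all 1000 random lists. These lists were already matched on mean expression, so this says little about intensity-dependent normalization. A low empty vector array is argued against by the sea urchin PRDM14 median of 0.058 against mouse PRDM14, also above all 1000 random lists. Extra copies of the chromosome in some of the cells would raise its whole length, and 10 of 10 runs of consecutive genes had a median above 0 on both arrays, so this is a candidate explanation; no DNA measurement was used here. Chromosome 16 was higher only with CBFA2T, at 0.072 against the empty vector with 9 of 10 runs above 0 (lowest -0.015), and Dppa2 lies on it. An effect of the sea urchin protein on these genes was not tested.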

How the results depend on the processing

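No paired analysis was possible because each group had 1 array and the results come from no test. At 1.5-fold the genes higher and lower numbered 35 and 20 for mouse PRDM14 against the empty vector, 41 and 19 for sea urchin PRDM14, 62 and 37 for sea urchin PRDM14 and CBFA2T, and 38 and 24 between the sea urchin arrays; against mouse PRDM14 they numbered 36 and 26 without CBFA2T and 53 and 36 with it, as a lower threshold must give. Without the symbols that the naming rule leaves out, which keeps the small RNAs Rny1 and AF357355, 3 genes were higher for mouse PRDM14 and 2 for sea urchin PRDM14. With no filter, 2 genes were lower for sea urchin against mouse PRDM14, and with the stricter filter 4 were lower for the CBFA2T array against mouse PRDM14, as more or fewer genes were counted. The correlation of 0.09 between the differences without a shared array was 0.067 with no filter, 0.114 with the stricter filter and 0.11 (0.1105) without those symbols; the cause was not tested. The response to CBFA2T of genes higher with mouse PRDM14 (-0.18) turned to 0.033 with the stricter filter, 0.033 at 1.5-fold and 0.30 without those symbols, so it has no settled direction. That of the lower genes (-0.94) was -1.38 with the stricter filter, -1.23 after cyclic loess and -0.14 at 1.5-fold; the cause was not tested. Of the 19 list results outside the random lists, 14 stayed outside in all 6 alternatives for lists and 5 did not in at least 1. Of 138 values of named genes, 2 slipped under 2-fold after cyclic loess, Gja1 (-0.997) and Epha2 (-0.997). Leaving out chromosomes 11 and 16, chosen after the data were seen, kept 10612 of 12042 genes. The genes higher for the CBFA2T array fell from 19 to 13 against the empty vector and from 16 to 11 against sea urchin PRDM14. These calls were thus more frequent on the 2 chromosomes than elsewhere. No other count moved by as large a share. Dim genes, with values near the filter, have the least certain folds.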

Other observations

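The mitochondrial genes and the neighbours of Rex2 and Rian below were chosen after their values were seen, and no explanation of them was tested.

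Genes of the mitochondrial genome lay slightly higher on all 3 PRDM14 arrays than on the empty vector array, none of them 2-fold and with the exception of ND3 with mouse PRDM14 (-0.02). Over 10 genes the median difference was 0.19 with mouse PRDM14 (percentile 99.6), 0.17 with sea urchin PRDM14 (percentile 98.9) and 0.28 with CBFA2T added (percentile 99.8). ND1 differed by 0.27, 0.21 and 0.30. After cyclic loess the medians were 0.14, 0.09 and 0.20. All 3 comparisons share the empty vector array, and between the sea urchin and mouse PRDM14 arrays the median was -0.01. The array with CBFA2T lay above the sea urchin PRDM14 array by a median of 0.10 (percentile 96.5, 10 of 10 genes above 0) and above the mouse PRDM14 array by 0.11 (percentile 92.7, 9 of 10 above 0), both inside the random lists.

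Rex2 lies among zinc finger genes on chromosome 4. Of the 11 genes made of Rex2 and the 5 on each side of it past the filter, 9 were above 0 in each of the 3 comparisons with the empty vector, with medians of 0.20, 0.28 and 0.41. Zfp992 differed by 1.09, 0.82 and 1.18 and Zfp981 by 0.27, 1.38 and 1.46 with mouse PRDM14, sea urchin PRDM14 and CBFA2T added, while Gm13149 differed by 0.00, 0.06 and -0.13. Genes this alike can share probes.

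Rian and AF357355 on chromosome 12 were lower with mouse PRDM14 and with CBFA2T added, but of the 11 genes around Rian no others passed 2-fold against the empty vector. AF357425 differed by -0.91 with mouse PRDM14, 0.26 with sea urchin PRDM14 and -0.58 with CBFA2T added. AF357355 was at 6.95 with the empty vector, 4.98 with mouse PRDM14, 7.55 with sea urchin PRDM14 and 5.72 with CBFA2T added.

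Bmp4, a signalling ligand gene, was at 6.89 with mouse PRDM14 and at 6.10, 5.69 and 5.74 with the empty vector, sea urchin PRDM14 and CBFA2T added. Among 5567 probe sets past the filter with no gene listed, 73 were at least 2-fold higher and 52 lower with mouse PRDM14, 73 and 43 with sea urchin PRDM14, and 104 and 51 with CBFA2T added. Among 893 probe sets of several genes the counts were 1 and 0, 1 and 1, and 32 and 0.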
